A study of Mus with 78 samples.

How the data were processed

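Total RNA was extracted from mouse cerebella with a column kit, and only RNA with an integrity number above 8 was used, per the labels' protocols. Stranded mRNA libraries were made with the TruSeq kit and sequenced on an Illumina NovaSeq6000. The same protocol text also describes cell suspensions for flow cytometry, which are not part of these measurements. The submitters' processing notes name Trim Galore, STAR and the mouse genome build GRCm39, without versions. The counting tool, its strand setting and the annotation release were not given in the sources used here, so reads of overlapping or antisense genes may be assigned to either. Each deposited file holds whole-number counts per gene ID for 1 lane of 1 library, not normalized, in a single value column. The 78 files list the same 55359 versioned Ensembl IDs and 1 line with a blank ID, which held 0 counts (a share of 0) and was left out. No other column of values was present.

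The 2 lanes of each library were summed, which gave 39 libraries. The library number was taken as the animal, since the design text calls the libraries biological replicates. Groups were genotype (WT or KO), age (adult or P30) and sex, as labelled. Library numbers 1 to 39 are not shared between groups and follow the order of the groups, and preparation batches were not given, so that no batch could be separated from the groups. The titles carry another number, different for each of the 39 libraries. Some of these numbers follow each other across genotypes, but the labels do not say what they mark or give litters, and they were not used.

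IDs were kept by edgeR's filterByExpr by group (minimum count 10), which left 19158. Normalization factors were computed by TMM, and CPM values use the scaled library sizes. A model with 1 mean per group was fitted to all 39 libraries with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3). IDs were called at a Benjamini-Hochberg adjusted p under 0.05. The adult and P30 KO effects are the mean of the female and male differences. All tests were two-sided. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F. The tests, samples, alternatives and the rule for named genes were fixed before the data were examined. The comparisons of KO with WT over all ages and sexes and of adult with P30 in KO were fitted in the same model without having been fixed.

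The rule for named genes asked for up to 8 genes per direction with the largest log2 fold change among those called, with a mean log2 CPM over 0 and the same direction in both strata averaged. Because the files do not pair IDs with symbols, and the reference table (RefSeq genes of GRCm38.p6) matched 0 of 55359 IDs, it was held to 2 IDs per direction and comparison. ENSMUSG00000107858.2, which has a mean log2 CPM below 0, and the values of ENSMUSG00000039419.18 outside the adult comparison are given beyond that rule and were chosen after their values were seen. For the same reason, the 36 gene lists (588 genes) fixed beforehand, the level of Cntnap2 and the genes near Cntnap2 were not analysed by name here.

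Alternatives were DESeq2's size factors in edgeR, no filter on low counts, a stricter filter (CPM of at least 1 in at least 4 libraries), DESeq2 1.42.0, limma voom with sample quality weights (limma 3.58.1), a fit to the groups of the contrast alone, 3 surrogate variables from svaseq (sva 3.50.0), each lane alone, and leaving out each library in turn. Chosen after seeing the data were leaving out libraries 10 and 22 together, limma voom without weights, quality weights without libraries 10 and 22, and robust empirical Bayes. An unstranded column planned as an alternative did not apply, since the files hold 1 value column.

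The code was tested on simulated counts for 19158 IDs, with 200 IDs changed by a known fold. Counts were drawn independently around a single mean per ID, with no outlying libraries, and IDs of low level were not changed. In the adult comparison edgeR recovered 57.5%, 91% and 97.5% of IDs changed 1.5-fold, 2-fold and 3-fold, with 6, 14 and 10 false calls. In the P30 comparison it recovered 66.5%, 94.5% and 99%, with 6, 8 and 15 false calls. Other splits of the libraries were drawn 100 at a time, the real one included, by permuting the labels within the other factors. For KO against WT a second draw of 100, in which no split of any age and sex recurred, was made after the first had been seen. The single age and sex comparisons use the second draw, since 67 to 74 of the first 100 splits were distinct for them. Count floors cover counting error only, whereas SDs and SEs include the spread between libraries.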

Results

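RNA was sequenced from the cerebella of mice labelled as Cntnap2 knockouts and of wild-type (WT) mice. Cntnap2 is a cell adhesion molecule of the neurexin family that is best known from axons and from its link to autism. The series title places the work in a study of oxidative stress and inflammation in these mutants. The 39 libraries, numbered 1 to 39 and each sequenced on 2 lanes, were described as biological replicates of 8 groups defined by genotype, age and sex. WT adult females, WT adult males and knockout (KO) adult females had 5 libraries each, and KO adult males had 4. At postnatal day 30 (P30), each of the WT male, WT female, KO male and KO female groups had 5 libraries. The age of the adults was not given in the sources used here. Summed over both lanes, the total ranged from 26447751 to 38445024 counts per library, with a median of 33205227, and 19158 of 55359 gene identifiers (IDs) had enough counts to be tested. A count of 0 in the smallest library allows up to 3 counts, and such limits cover counting error only.

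The 2 lanes of a library agreed closely, with a chi-square per degree of freedom between 1.21 and 1.29. Between libraries of one group it lay between 8.87 and 597. No 2 libraries of a group were therefore alike within sampling noise, and each was counted once. Libraries 10 (WT adult male) and 22 (WT P30 male) stood apart from their groups, with a median correlation of 0.903 and 0.951 with the rest of their group against 0.981 for the next lowest library, number 19 (KO adult male). One ID took the most counts in 37 of the 39 libraries. Its share was 2.45% ± 0.57 (SD, n = 5) in KO adult females, 2.25% ± 0.64 (SD, n = 4) in KO adult males, 1.94% ± 0.33 (SD, n = 5) in WT adult females and 1.55% ± 0.30 (SD, n = 5) in WT adult males, so that the genotypes overlapped within their spread. Libraries 10 and 19 were led by another ID, ENSMUSG00000119584.1, with 1.43% and 3.61% of their counts.

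**Figure D1:**
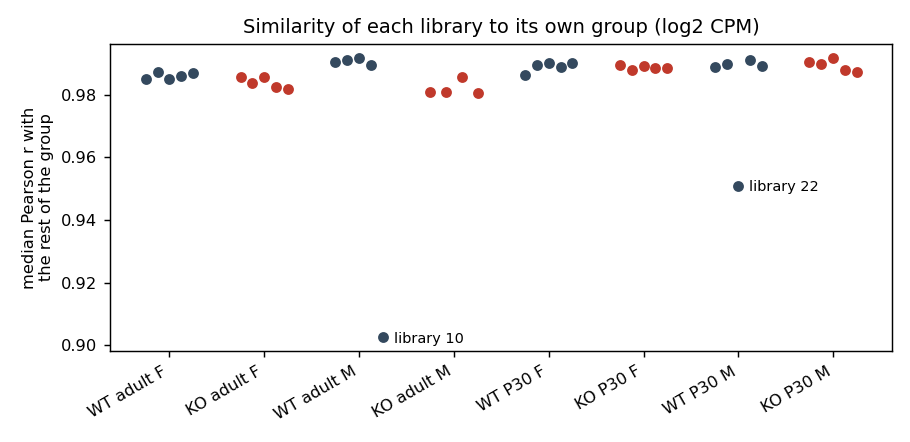
Each point is 1 of the 39 libraries, placed by its group on the horizontal axis and by its median Pearson correlation (log2 CPM over the tested IDs, no unit) with the rest of its group on the vertical axis. Libraries 10 and 22 lie at 0.903 and 0.951, below all others.

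The files do not pair IDs with gene names, and the reference table used here matched 0 of the 55359 IDs. Which ID stands for Cntnap2 was therefore not known here. Its level, the usual first check of a knockout label, is not given by name, although its ID may be among those below. The gene lists fixed for oxidative stress, inflammation and cell types were not analysed for the same reason. The comparisons below are given by ID.

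The first comparison asked which genes differed between KO and WT cerebella in adults. A single ID passed the test, and it was lower in KO. ENSMUSG00000039419.18 stood at 23.2 ± 13.2 CPM (SD, n = 5) in KO adult females against 90.8 ± 21.9 CPM (SD, n = 5) in WT adult females, and at 19.5 ± 5.19 CPM (SD, n = 4) in KO adult males against 120 ± 45.4 CPM (SD, n = 5) in WT adult males. Its log2 fold change was -2.29 ± 0.35 (SE), a level of 20.4% of WT, with an adjusted p of 0.00325 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It remained past the threshold under every alternative run, and without each library in turn. Within each sex the ranges of KO and WT did not overlap, with KO libraries at up to 45.5 CPM in females (library 13) and 24.99 CPM in males, and WT libraries from 54.7 CPM in females (library 4) and from 42.3 CPM in males (library 10). A second ID, ENSMUSG00000107858.2, did not pass in adults in edgeR (log2 fold change 2.63 ± 0.51 SE, adjusted p = 0.0964), passed in 9 of 30 alternatives (adjusted p from 0.000691 to 0.41) and was near the detection limit, at 0.425 ± 0.264 CPM (SD, n = 5) in KO adult females and 0.0467 ± 0.0616 CPM (SD, n = 5) in WT adult females.

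The number of IDs called in adults depended on the tool and on a few libraries. edgeR called 1 ID, and 2782 IDs had an unadjusted p under 0.05, or 4401 without libraries 10 and 22. About 957.9 of the 19158 IDs would have such a p if no ID differed. DESeq2 called 122 IDs (106 higher and 16 lower in KO), limma voom without weights called 2, and limma voom with sample quality weights called 5888 (3141 higher and 2747 lower). The edgeR count was 131 with libraries 10 and 22 both left out, 391 without library 19, 36 without library 4, 4 without library 9 and 2 without library 3. The differences called by limma with quality weights were small, with a median absolute log2 fold change of 0.32, and 127 of the 5888 exceeded 2-fold.

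**Figure D2:**
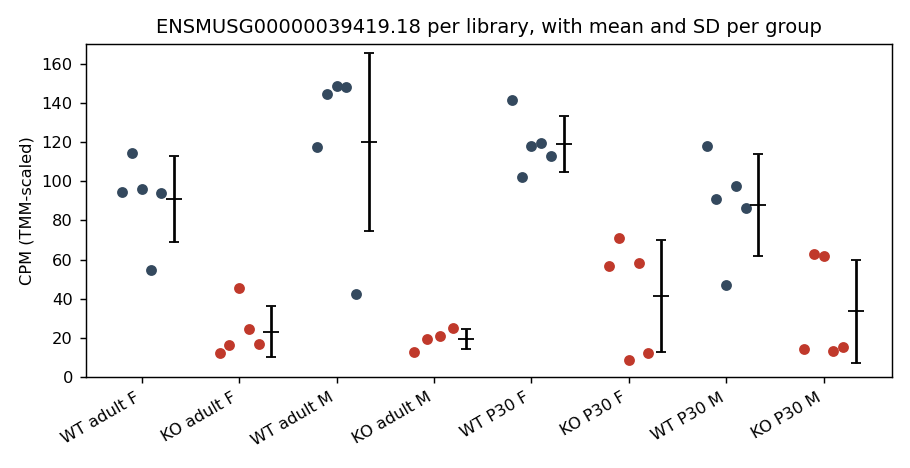
The level of ENSMUSG00000039419.18 in CPM (vertical axis) is shown for each library by group, WT in dark blue and KO in red, with bars for the group mean and SD. All 10 WT P30 libraries lie at 47.2 CPM or more, whereas the 10 KO P30 libraries spread from 8.84 to 71.0 CPM.

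The same question was asked at P30, where no ID passed in edgeR. ENSMUSG00000039419.18 was measured at 41.5 ± 28.7 CPM (SD, n = 5) in KO females against 119 ± 14.3 CPM (SD, n = 5) in WT females, and at 33.5 ± 26.2 CPM (SD, n = 5) in KO males against 87.9 ± 25.8 CPM (SD, n = 5) in WT males. Its log2 fold change of -1.46 ± 0.33 (SE) did not pass (adjusted p = 0.813 in edgeR), and it passed in 2 of 33 alternatives (adjusted p from 0.00219 to 1). The KO libraries did not form a tight group. Libraries 37, 39, 33, 30 and 34 had 8.84, 12.5, 13.5, 14.4 and 15.2 CPM, and libraries 35, 38, 32, 31 and 36 had 56.8, 58.1, 61.7, 62.7 and 71.0 CPM. ENSMUSG00000107858.2 had the lowest adjusted p, 0.0516, with a log2 fold change of 3.21 ± 0.58 (SE) from 0.0380 ± 0.0541 CPM (SD, n = 5) in WT females to 0.328 ± 0.240 CPM (SD, n = 5) in KO females. It passed in 9 of 32 alternatives, with adjusted p from 0.0016 to 0.99.

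At P30, 502 IDs had an unadjusted p under 0.05 in edgeR, or 272 without library 22 and 799 without library 20. These numbers are below the 957.9 expected if no ID differed. DESeq2 called 1 ID, limma voom without weights called 0 and limma voom with quality weights called 4. Leaving out library 20, 29, 34 or 35 brought the edgeR count to 1. In simulated data built on these libraries, edgeR recovered 66.5% of 200 IDs changed 1.5-fold and 94.5% of 200 IDs changed 2-fold at P30. In the adult comparison it recovered 57.5% and 91%. The simulated counts were drawn independently, without libraries that stand apart, so these rates need not hold for the real libraries. ENSMUSG00000039419.18, 2.74-fold lower in KO at P30, did not pass in edgeR.

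Within each age and sex, the comparisons asked whether males and females differed from their own WT group. No ID passed in edgeR in adult females, adult males, P30 females or P30 males. ENSMUSG00000039419.18 had log2 fold changes of -1.97 ± 0.47, -2.62 ± 0.53, -1.52 ± 0.46 and -1.39 ± 0.46 (SE) in these groups, with adjusted p of 0.999, 0.244, 1 and 0.768 in edgeR. It passed in 2 of 23 alternatives in adult females (lowest adjusted p 0.0308), 5 of 22 in adult males (lowest 0.000785) and 0 of 23 in P30 females and in P30 males. Unadjusted p-values under 0.05 were found for 915 IDs in adult females, 2446 in adult males, 183 in P30 females and 939 in P30 males. Leaving out each library in turn gave 445 to 1396, 1345 to 3726, 140 to 285 and 250 (without library 22) to 1988 (without library 20). If no ID differed, 957.9 would be expected, and with all libraries only the number in adult males was above that. In adult females, DESeq2 and limma voom without weights called 0 IDs and limma voom with quality weights called 840. In adult males these tools called 2, 0 and 3655 IDs, and edgeR called 25 without library 19 and 2 without library 9. In P30 females and P30 males all of them called 0.

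Whether the KO effect differed between ages or between sexes was tested directly. For the difference between adults and P30, edgeR called 0 IDs (1194 with an unadjusted p under 0.05, or 2750 without library 10 and 2123 without library 22), DESeq2 and limma voom without weights called 0, and limma voom with quality weights called 4152. With surrogate variables in the design, edgeR called 228. For ENSMUSG00000039419.18 this difference was -0.84 ± 0.46 on the log2 scale (SE, adjusted p = 0.82 in edgeR). The KO P30 libraries in these comparisons had from 7.49% to 69.2% of the WT median of that ID. For the difference between females and males, edgeR called 0 IDs (833 with an unadjusted p under 0.05, or 299 without library 10, 302 without library 22, 268 without both and 1599 without library 9), and DESeq2 and limma voom with and without quality weights called 0 as well. The number of 833 is below the 957.9 expected if no ID differed.

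Averaged over both ages and both sexes, a comparison that was fitted with the others but was not among those fixed beforehand, 2 IDs passed in edgeR. ENSMUSG00000039419.18 was lower in KO by -1.88 ± 0.24 on the log2 scale (SE, adjusted p = 6.14e-05), and ENSMUSG00000107858.2 was higher by 2.92 ± 0.38 (SE, adjusted p = 6.14e-05). Both were called without each of the 39 libraries in turn. In the deposited order of 55359 IDs they stand close together, at positions 16943 and 16945. What that order follows was not given, and whether the 2 changes are separate effects was not tested. Under the stricter filter on low counts the second was not tested and 1 ID was called. limma voom with quality weights called 2942 IDs.

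**Figure D3:**
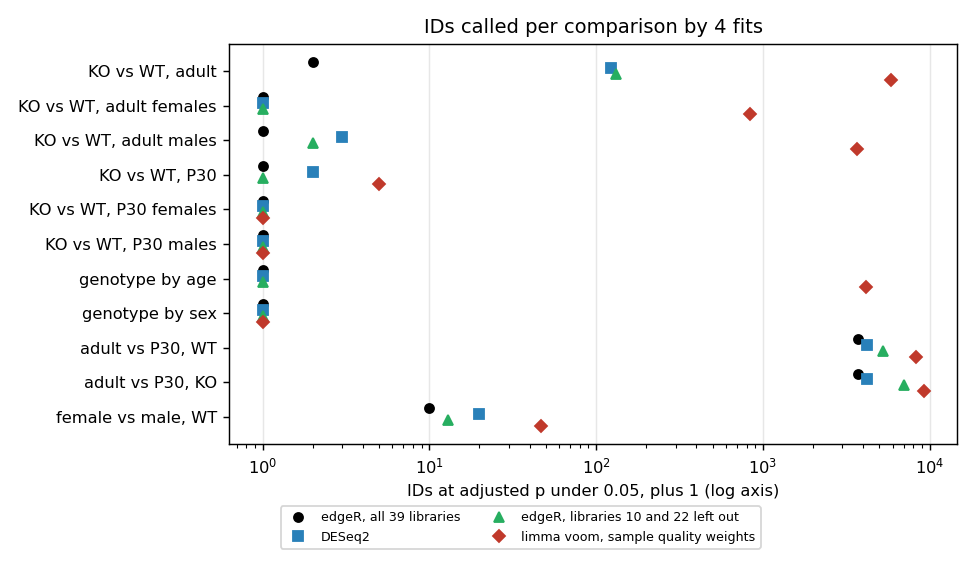
The number of IDs called per comparison, plus 1, is shown on a log axis for edgeR on all 39 libraries, DESeq2, edgeR without libraries 10 and 22, and limma voom with sample quality weights. For KO against WT in adults these were 1, 122, 131 and 5888 IDs, and for adult against P30 in WT they were 3721, 4208, 5281 and 8237 IDs.

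Adult and P30 cerebella of WT mice differed in 3721 IDs in edgeR, where adult KO and WT differed in 1, but with quality weights the counts were 8237 and 5888. Of 19158 IDs, 1954 were higher and 1767 lower in adults in edgeR, and 593 of these differed more than 2-fold (435 higher and 158 lower). ENSMUSG00000115529.2 fell from 11.1 ± 1.26 CPM (SD, n = 5) in P30 females to 0.960 ± 0.659 CPM (SD, n = 5) in adult females, and from 9.59 ± 1.57 to 0.924 ± 0.301 CPM (SD, n = 5 each) in males, a log2 fold change of -3.44 ± 0.20 (SE, adjusted p = 9.47e-15 in edgeR). ENSMUSG00000062345.11 fell from 3.25 ± 1.25 to 0.158 ± 0.150 CPM (SD, n = 5 each) in females (log2 fold change -4.46 ± 0.35 SE over both sexes, adjusted p = 1.36e-11 in edgeR). ENSMUSG00000104674.2 rose from 0.575 ± 0.462 to 5.47 ± 2.78 CPM (SD, n = 5 each) in females and from 0.952 ± 0.543 to 5.65 ± 1.78 CPM in males (2.90 ± 0.29 SE, adjusted p = 5.05e-09 in edgeR). ENSMUSG00000021342.15 was called higher as well (4.13 ± 1.17 SE, adjusted p = 0.0121 in edgeR), but its adult female level of 16.5 ± 21.3 CPM (SD, n = 5) varied more than its mean, and the call was lost without library 10 (1.68, adjusted p = 0.631). Over all alternatives its adjusted p ranged from 0.00756 to 0.685. Leaving out library 22 raised the number of called IDs from 3721 to 5808.

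The same contrast in KO mice, also fitted beyond those fixed beforehand, gave 1856 IDs higher and 1879 lower in adults. ENSMUSG00000115529.2 (log2 fold change -3.004 ± 0.20 SE) and ENSMUSG00000062345.11 (-4.36 ± 0.36 SE) fell and ENSMUSG00000104674.2 (3.43 ± 0.31 SE) rose, with adjusted p of 5.16e-13, 7.59e-11 and 5.09e-10 in edgeR. ENSMUSG00000065701.3 was called higher (6.12 ± 1.11 SE, adjusted p = 0.000152), with 27.5 CPM in library 19, and its log2 fold change was 3.66 without that library. The WT and KO comparisons used different libraries. They shared 941 IDs higher in adults, against 189.3 expected of independent lists, and 1070 lower, against 173.3 expected, and 0 IDs were called in opposite directions. Both lists came from the same fit and filter, so independent lists are only a rough reference. In both genotypes the adult libraries precede the P30 libraries in number, so a batch that follows this order could give the same overlap. Of the 3721 IDs called in WT, 3596 (96.6%) had the same direction in KO.

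**Figure D4:**
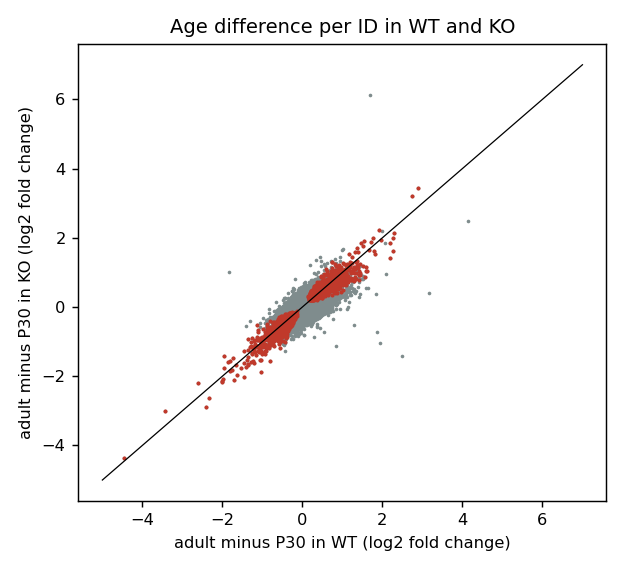
Each point is 1 ID with a mean log2 CPM over 0, placed by its log2 fold change between adults and P30 in WT (horizontal) and in KO (vertical). Red marks IDs called in both, all of them in the same direction, and the line marks equal change.

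Females and males of the WT genotype were compared as a check of the sex labels and as a reference for the size of a sex difference. edgeR called 9 IDs, 4 higher in females and 5 higher in males, and 3002 IDs had an unadjusted p under 0.05, or 1209 without library 10 and 1368 without library 22. The 5 IDs higher in males did not overlap between the sexes in any of the 39 libraries. ENSMUSG00000069045.12 ranged from 31.6 to 126 CPM in males and from 0 to 2.46 CPM in females (log2 fold change female minus male -9.04 ± 0.66 SE, adjusted p = 4.34e-12 in edgeR), and ENSMUSG00000068457.15 from 4.62 to 35.8 CPM in males and from 0 to 1.06 CPM in females (-9.14 ± 0.64 SE, adjusted p = 2.5e-12). ENSMUSG00000086503.5 was higher in females (9.34 ± 0.86 SE, adjusted p = 2.59e-09 in edgeR), with 542 ± 51.0 CPM (SD, n = 5) in WT P30 females and 2.02 ± 2.21 CPM (SD, n = 5) in WT P30 males. In WT adult females it had 365 ± 224 CPM (SD, n = 5), since library 5 had 4.70 CPM. ENSMUSG00000037369.18 was higher in females by 0.84 ± 0.17 (SE, adjusted p = 0.0331 in edgeR), a call lost without library 1, 2, 3, 4, 8, 20, 22, 25, 26, 28 or 29, with adjusted p between 0.0548 and 0.122, and its adjusted p ranged from 0.000000444 to 0.548 over all alternatives.

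**Figure D5:**
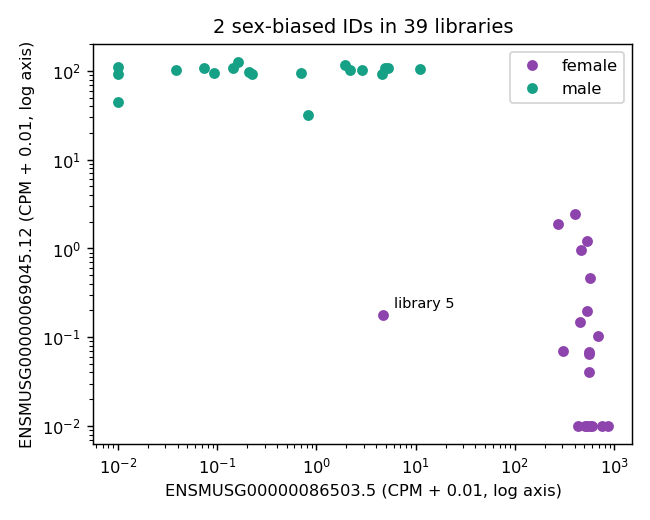
Each point is 1 of the 39 libraries, with the level of ENSMUSG00000086503.5 (horizontal) and of ENSMUSG00000069045.12 (vertical), both in CPM plus 0.01 on log axes. Females and males separate on the vertical axis, and library 5, a WT adult female, has 4.70 CPM on the horizontal axis, below the 274 CPM or more of the other females.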

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

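The tests of depth and of abundant IDs for libraries 10 and 22, of a single X chromosome for library 5, and of other splits for the age and sex comparisons and for adults without libraries 10 and 22 were set before their results were seen. The other tests in this part were chosen afterwards. Values far from the rest of their group were sought in 112 sets of 4 or 5 libraries, each for a measure within 1 of the 8 groups. In all, 24 were found, where independent values would give about 1 in 20, or 5.6. The measures are not independent, most are IDs named because they were called, and libraries 10 and 22 recur, so these numbers are not a test.

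Libraries 10 and 22 were far from their groups in several measures. Their median correlations with their group were 0.903 (others of the group from 0.990 to 0.992) and 0.951 (others from 0.989 to 0.991). When all libraries were thinned to the smallest total of 26447751 counts, both were still the lowest 2 of the 39 (0.904 and 0.951), and without the 20 most abundant IDs both were again the lowest 2 (0.902 and 0.951), which argues against depth and against a few abundant IDs as the cause. RNA quality, dissection and the animals themselves stay open, and no biological explanation was tested, since the labels give none that sets these animals apart.

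Library 10 also stood apart with log2 CPM of 3.16 for ENSMUSG00000021342.15, 1.45 for ENSMUSG00000104674.2, 3.39 for ENSMUSG00000037369.18, 2.23 for ENSMUSG00000068457.15, 4.98 for ENSMUSG00000069045.12 and 5.40 for ENSMUSG00000039419.18. Library 22 stood apart with 4.25 for ENSMUSG00000037369.18, 3.17 for ENSMUSG00000068457.15 and 5.50 for ENSMUSG00000069045.12.

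Library 5, labelled a WT adult female, had a log2 CPM of 2.25 for ENSMUSG00000086503.5, against 8.24 to 9.11 in the other 4 libraries of its group. A male animal labelled female is argued against, since the 5 IDs higher in males reached at most 0.925% of the male median there. An animal with a single X chromosome would hold the other IDs higher in females at the male level, and all 3 of them lay nearer the median of WT adult males than that of the other WT adult females (48.5 CPM against 42.4 and 66.2, 61.6 against 59.9 and 91.5, and 7.44 against 6.32 and 9.34). For the first and the last of them, however, library 5 lay between the sexes. It was above the highest WT adult male (45.9 and 6.83 CPM) and below the lowest other WT adult female (53.9 and 8.21 CPM). Loss of an X chromosome in this animal is therefore only a hypothesis, since 3 IDs in 1 library cannot exclude other causes of low levels and the files do not give the chromosome of an ID.

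In KO adult males, library 19 was high for ENSMUSG00000065701.3 (log2 CPM 4.78, others from -2.14 to -1.47) and low for ENSMUSG00000068457.15 (4.70). Library 18 had a median correlation of 0.986 with its group, above the 0.981 of the others, and library 16 had a log2 CPM of -0.328 for ENSMUSG00000115529.2. In KO adult females, library 13 had 1.04 for ENSMUSG00000115529.2 and library 14 had -0.159 for ENSMUSG00000068457.15, an ID higher in males. In WT adult females, library 4 had 5.78 for ENSMUSG00000039419.18.

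In KO P30 males, library 34 had 2.16% of its counts in the ID with the most counts (others from 1.40% to 1.59%) and a log2 CPM of -1.54 for ENSMUSG00000021342.15. Library 32 had -0.215 for ENSMUSG00000104674.2 and library 33 had 6.01 for ENSMUSG00000037369.18. In KO P30 females, library 39 had 6.14 for ENSMUSG00000037369.18.

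Other splits of the libraries were set against each count in edgeR. For adult against P30, 1 of 100 splits, the real one, gave as many IDs in WT (3721, highest other 3388) and in KO (3735, highest other 0), a share under 0.05 for both. For females against males in WT, 2 of 100 splits gave as many as 9 (highest other 1972). For KO against WT over all ages and sexes 2 of 100 gave as many as 2 (highest other 656), or 2 of 100 in the second draw (highest other 2). These shares are under 0.05 too. No share was corrected for the number of comparisons, and other splits gave as many or more IDs here, so for these counts chance is less likely but not excluded. The 5 IDs higher in males did not overlap between the sexes in any of the 39 libraries, including the KO libraries, which were not part of that contrast. This argues against chance for those 5 IDs. For KO against WT in adults, 7 of 100 splits gave at least the real count of 1 in the first draw (highest other 1867) and 4 of 100 in the second (highest other 5548). The shares lay on either side of 0.05, a difference that 2 draws of 100 can give, so chance stays open for the count. They count IDs of any kind and were not a test of ENSMUSG00000039419.18 itself, whose KO and WT ranges did not overlap within either adult sex. With libraries 10 and 22 left out, 7 of 100 splits gave at least the real 131 (highest other 5264), so chance was not excluded there. Counts of 1867 and more thus came from splits that mix the genotypes, and which libraries those splits set apart was not tested.

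For the 7 comparisons in which edgeR called 0 IDs, 100 of 100 splits necessarily gave at least as many, so the splits say nothing about these counts. The highest other counts in the first and second draw were 0 and 0 for KO against WT at P30, 4 and 115 in adult females, 3517 and 4321 in adult males, 0 and 0 in P30 females, 1 and 0 in P30 males, 4 and 4148 for the difference between ages, and 1 and 3 for the difference between sexes.

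For the numbers of IDs with an unadjusted p under 0.05 in edgeR, chance was not excluded in any comparison of KO with WT. In the first and second draw, 24 and 17 of 100 splits gave as many as 2782 in adults (highest other 5749 and 7823), and 24 and 28 gave as many as 502 at P30 (1633 and 1808). Splits with as many as the real count were 21 and 22 for 915 in adult females (highest other 3650 and 3221), 64 and 63 for 2446 in adult males (6975 and 7311), 56 and 68 for 183 in P30 females (706 and 683) and 27 and 30 for 939 in P30 males (1819 and 2157). They were 39 and 37 for 1194 for the difference between ages (4571 and 7131) and 48 and 44 for 833 for the difference between sexes (4727 and 4144). For females against males in WT, 24 of 100 splits gave as many as 3002 (highest other 7057), which does not exclude chance for that count.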

How the results depend on the processing

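Libraries 10 and 22 left out (with and without quality weights), limma voom without weights, all alternatives for the comparisons not fixed beforehand and robust empirical Bayes were chosen after seeing the data. No paired analysis was possible because neither library numbers 1 to 39 nor the other numbers in the titles are shared between groups, and no litter or batch was given. The gene lists, the level of Cntnap2 and the genes near Cntnap2 were not run by name, and an unstranded column was not run. ENSMUSG00000039419.18 kept its direction and call in adults in all alternatives run. Of the values of single IDs under alternatives, 846 kept their side of the threshold, 29 gained a call, 19 lost it and 0 changed direction. The causes of the changes below were not tested, except that fits without libraries or groups use fewer samples. DESeq2 gave no adjusted p for ENSMUSG00000069045.12 between the sexes. Depth limits ENSMUSG00000107858.2, which had 0 to 27 counts per library.

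For KO against WT in adults (1 ID), DESeq2 gave 122, quality weights 5888, surrogate variables 6, libraries 10 and 22 left out 131, limma voom without weights 2 and quality weights without libraries 10 and 22 6473. Leaving out each library gave 1 to 391. At P30 (0 IDs), no filter, DESeq2 and surrogate variables gave 1 each, and quality weights gave 4 with and 4 without libraries 10 and 22. Leaving out each library gave 0 to 1. In adult females (0), quality weights gave 840, and 1253 without libraries 10 and 22. In adult males (0), DESeq2 gave 2, quality weights 3655, libraries 10 and 22 left out 1, and both together 4394. Leaving out each library gave 0 to 25. For the difference between ages (0), quality weights gave 4152, surrogate variables 228, and quality weights without libraries 10 and 22 4450. Over all ages and sexes (2), the stricter filter gave 1 and quality weights 2942, or 3546 without libraries 10 and 22.

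For adult against P30 in WT (3721), quality weights gave 8237, or 8290 without libraries 10 and 22, and a fit to its own groups 2345. Surrogate variables gave 2798 (1306 higher and 1492 lower in adults), of which 1599 were among the 3721. Leaving out each library gave 2974 to 5808. In KO (3735), quality weights gave 9295, or 9466 without libraries 10 and 22, its own groups 6003 and libraries 10 and 22 left out 7032. Between the sexes (9), DESeq2 gave 19, quality weights 46, or 85 without libraries 10 and 22. The share higher in females was 44.4% in edgeR and ranged from 16.7% (a fit to its own groups) to 58.3% (surrogate variables). It was 54.5% without library 5. The set of called IDs differed between these fits, and none of the IDs followed singly changed direction. In the other comparisons leaving out a library moved no number of called IDs by over 1.5 times. The numbers with an unadjusted p under 0.05 moved by more than that under some alternative in every comparison.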

Other observations

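All tests in this part were chosen after the result they bear on had been seen.

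With sample quality weights, which let a library far from its group count less (weights of 0.036 for library 10 and 0.0686 for library 22), limma called 5888 IDs between KO and WT adults, 780 of them changed more than 1.5-fold, and 1 of 100 splits, the real one, gave as many (highest other 5776), or 2 of 100 in the second draw (highest other 7418). The share was also under 0.05 for the 4152 IDs of the difference between ages (1 of 100 splits, highest other 2855, and 2 of 100 in the second draw, highest other 6379). The same held for the 2942 IDs over all ages and sexes (3 of 100, highest other 4116, and 2 of 100, highest other 4018). For the 3655 IDs in adult males the shares lay on either side of 0.05, with 6 of 100 in the first draw (highest other 5883), where splits recurred, and 3 of 100 in the second (highest other 5806). The second draw, used for a single age and sex, was made after the first had been seen, so chance stays open there. The share was not under 0.05 for the 840 IDs in adult females (32 and 36 of 100) or the 4 IDs at P30 (8 and 11 of 100). No share was corrected for the number of comparisons, so a share under 0.05 does not exclude chance. The log2 fold changes of adult females and adult males, which share no library, had a correlation across IDs, which are not independent replicates, of 0.622 with quality weights (1 of 100 splits as high, highest other 0.596, and 2 of 100 in the second draw, highest other 0.637) and 0.575 in edgeR without libraries 10 and 22 (2 of 100), but of 0.245 in edgeR on all libraries (29 and 25 of 100), which does not exclude chance. A widespread adult KO effect of small size is a hypothesis. It rests on the fits with quality weights and on the correlation in edgeR without libraries 10 and 22, since edgeR on all libraries called 1 ID in adults. The shares for that count were 7 and 4 of 100 in the 2 draws. Of the 122 IDs called by DESeq2 and the 131 called by edgeR without libraries 10 and 22, 121 and 131 were among the 5888, but these fits share libraries. Preparation batches that follow the group order cannot be told from genotype here. With libraries 10 and 22 left out, quality weights gave 6473 IDs and edgeR 131, and which libraries' weights produce the larger count was not tested.

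The level of ENSMUSG00000039419.18 ranged among the KO P30 libraries from 7.49% to 69.2% of the median of WT libraries of the same sex and age. A swap of KO and WT animals is argued against, since 0 of the 20 WT libraries lay at or below the median of the KO libraries, and so is RNA from libraries of the other sex, since the other sex's IDs reached at most 2.79% of their level in any KO P30 library. That some animals kept 1 intact copy of a gene that the others lack stays open. Of the 10 libraries, 5 lay nearer 50% of the WT median than that median or the lowest KO library of their age and sex. So did 2 of the 9 KO adults (libraries 13 and 14, at 48% and 25.8%) and 3 of the 20 WT libraries (4, 10 and 22, at 57.8%, 29.2% and 52%). Such a level alone therefore does not mark 1 intact copy. Libraries 10 and 22 stood apart from their groups in other IDs too, so their levels do not argue against it. The 5 KO P30 libraries had 56.8 to 71.0 CPM, and the rest of the KO P30 libraries 8.84 to 15.2 CPM. Of the 5, the females 35, 36 and 38 stood at 48.2%, 60.2% and 49.2%, but the males 31 and 32, at 69.2% and 68.1%, lay close to the point where the WT median is nearer and above the 47.2 CPM of WT male library 22. RNA of WT animals of the same sex mixed into some libraries would look alike and was not tested, and no library was left out or regrouped by this level, because that would select samples by the outcome.

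ENSMUSG00000086503.5, called higher in females, was found in males at 11.1 CPM in library 17, a KO adult male, or 2.09% of the female median, and the IDs higher in males reached 2.79% of the male median in library 39 and 2.49% in library 14, both KO females.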
